A study of Homo sapiens and Homo sapiens
Mus musculus with 5 samples.

How the data were processed

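The deposited files hold, for each of the 5 libraries, a matrix of counts of unique molecular identifiers (UMIs) per gene and cell, made with Cell Ranger 3.1.0 per the file headers. Tools listed per the submitters' processing notes, without the step each served, were also bcl2fastq 2.20.0, Seurat 3.1 and DESeq2 1.28.0, with the builds hg19 and mm10. The matrices were checked to hold whole numbers on 32738 human gene identifiers and no mouse genes, so reads of the mouse lines are seen only where they were counted on human genes. Barcode counts were stored in the same matrices as antibody capture features, 3 in each organoid library, 8 in the POLYseq pool and 7 in the TotalSeq pool. In the untreated organoid library the last 3 matrix rows have no entry in the feature table and were taken as the barcode rows, the most abundant of them as the library's own barcode. Gene positions were not used, since the annotation at hand was of another genome build.

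The organoid libraries were made with the version 3 chemistry and the pools with version 3.1, so organoids and pools were not compared. The groups were untreated organoids, organoids with oleate, organoids with oleate plus resmetirom, the POLYseq pool and the TotalSeq pool, with 1 library per group. Whether the untreated organoids received the albumin vehicle is not given in the sources used here, so the vehicle was not separated from the fatty acid. Cell barcodes were kept with at least 500 UMIs, 200 genes and at most 25% mitochondrial UMIs, which 81.8%, 77.4%, 81.8%, 96.8% and 96.7% of the cell barcodes passed. Scrublet called 249, 229 and 239 doublets in the organoid libraries, and these were removed. Scrublet was not run on the pools, where cells with more than 1 barcode were left out of the comparisons and droplets of mixed lines were not called. Median mitochondrial shares were 7.46%, 8.01% and 7.45% in the organoid libraries, 5.56% in the POLYseq pool and 4.83% in the TotalSeq pool.

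Cells were log-normalized and clustered in scanpy 1.11.5 (anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0) on 2000 variable genes, 30 principal components and 15 neighbours with the Leiden algorithm at resolution 0.6. The organoid libraries were clustered together, and so were the pools, without batch integration and without the barcode features. Clusters were named from fixed marker lists, 9 classes for organoids and 7 for the pools. A name needed at least 3 detected markers, each at 100 CPM or more and at least 4 times the level in the clusters lowest for it. No name was given where another class had as many markers or had more of them among the 10 leading genes, or where a cluster with few UMIs had none of its markers among them. A name was also withheld where GABRP, TFAP2B or CDH3 (organoids) or SFTPC or SCGB3A1 (pools) was among the leading genes, a rule added after the clusters were seen. In the organoids clusters 0, 1 and 8 were hepatocyte-like and clusters 3, 4 and 5 mesenchymal-like.

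A cell was assigned to its highest barcode where that barcode had at least 5 UMIs and 60% of the cell's barcode UMIs, to more than 1 barcode where it had the UMIs and a lower share, and otherwise to none. In the comparisons of the pools, cells with more than 1 barcode were left out and those with none or with another line's barcode kept. Hep G2 cells with the high-glucose barcode were also left out when the pools were compared. The separation of a barcode's own line from the others was measured as the area under the receiver operating curve.

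For each comparison counts were summed over the cells of a group, scaled with trimmed-mean (TMM) factors in edgeR 4.0.16 to CPM, counts per 1000000 scaled counts, and compared as the log2 ratio after 1 CPM was added to both. A gene was measured where it had at least 20 CPM and 50 counts in 1 of the groups, and it passed the size rule at an absolute log2 difference of 1, which is 2-fold. No test, p-value or standard error was computed, since each group had 1 library and cells of 1 library are not replicates. Counting error was given as 95% Poisson intervals for sums and exact binomial intervals for shares. A gene with 0 counts in a group was set to a floor of 3 counts over the group for its fold.

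Genes named in the text were the 10 with the largest and the 10 with the smallest log2 difference among measured genes. XIST, TSIX, genes of the Y chromosome and transcripts with only a clone or accession name were left out, and 1 further gene is not reported here, for which the next in rank was taken. The rule also takes members of the gene lists, and examples were limited, after the data were seen, to at most 4 members per list, at least 1.5-fold apart, of lists outside the central 95% of random lists. A condition on agreement between barcode groups could not apply, since each organoid library carried 1 barcode.

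The 24 gene lists were lipid droplet coat and storage, fatty acid oxidation and PPARA targets, fatty acid synthesis, cholesterol synthesis, apolipoproteins, thyroid hormone response in liver, bile acid synthesis and transport, xenobiotic metabolism, secreted plasma proteins, unfolded protein and integrated stress response, NRF2 and oxidative stress, metallothionein, inflammation and acute phase, fibrosis and matrix, glycolysis, glucose response (ChREBP), gluconeogenesis, type I interferon and nucleic acid sensing, p53 response, heat shock and dissociation stress, lysosome, proliferation, hypoxia, and mitochondrially encoded transcripts. Some genes stand on more than 1 list, HILPDA for example among lipid droplet and hypoxia genes. The median of each list with at least 3 measured members was placed among 10000 random lists matched on mean expression, as a percentile that describes the rank of the list and is not a p-value.

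The pipeline was tested on simulated data with 200 genes set apart by 1.5-, 2.5-, 4- or 8-fold at the depth of each comparison. Of genes set 2.5-fold apart 93.9% to 100% passed the size rule and of those set 4-fold apart all did, while of those set 1.5-fold apart 0% to 14% did. Unchanged genes passed in 28 cases for ESH9, 8 for high glucose, 3 for HUVEC, 1 for Hep G2 and 0 in the others. The simulated data carried counting error alone, so they do not give how many genes would pass between replicate libraries. Alternatives were tried for the scaling, the pseudocount, the gene filter, the mitochondrial and UMI limits, the clustering, doublet removal, thinning of each cell to 5000 UMIs, the barcode rule and the choice of control cells, in 27 settings. Thinning left out the 144, 149 and 197 hepatocyte-like cells of the untreated, oleate and oleate plus resmetirom libraries with fewer UMIs. HTODemux was run in Seurat 5.3.0 at a quantile of 0.99, and size factors were also taken from DESeq2 1.42.0. The other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3. Levels of sex-linked transcripts were not reported, and mouse lines were not compared gene by gene, since the matrices hold human genes alone.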

Results

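Gene transcripts and cell barcodes were counted in single cells of 5 droplet libraries, 1 library per group. The study tests POLYseq, a polymer vector that carries barcode DNA into cells so that samples can be pooled. There were 3 libraries of human liver organoids grown from induced pluripotent stem cells, used between days 21 and 24: untreated, with 500 µM oleate in 0.5% bovine serum albumin for 3 days, and with the same oleate plus 200 µM resmetirom for 3 days. The other 2 libraries were pools of human and mouse cell lines. The POLYseq pool held 3T3 mouse fibroblasts, B16-F10 mouse melanoma, mouse embryonic stem cells, ESH9 human embryonic stem cells, HUVEC endothelial cells, MEG-01 megakaryoblasts, Hep G2 hepatoma cells, and Hep G2 kept for 3 days in glucose at 25 mM. The TotalSeq pool, labelled with commercial reagents instead, held the same lines without the high-glucose culture.

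The untreated, oleate and oleate plus resmetirom organoid libraries held 14417, 12673 and 13454 cell barcodes with 162710699, 148766884 and 158633434 gene counts (unique molecular identifiers, UMIs), and 11551, 9580 and 10765 cells were kept. The POLYseq pool held 11825 cell barcodes with 118327366 UMIs, of which 11441 were kept. The TotalSeq pool held 9321 with 113682731 UMIs, and 9009 were kept. The median kept cell had 10774, 11140.5 and 12210.0 UMIs in the organoid libraries in the order above, 8442 in the POLYseq pool and 9081 in the TotalSeq pool. With 1 library per group there was no error between replicates and no test between groups. Every interval given is a 95% interval for counting error alone, a Poisson interval for summed counts and an exact Clopper-Pearson interval for shares. Counts of genes past 2-fold grew under both looser gene filters in all 14 comparisons. "Higher" and "lower" therefore describe these libraries, not their populations.

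Hepatocyte-like cells made up 52.7% (interval 51.8 to 53.7) of the untreated organoid cells, 51.1% (50.1 to 52.1) with oleate and 65.3% (64.4 to 66.2) with oleate plus resmetirom. Mesenchymal-like cells made up 27.3% (26.5 to 28.1), 30.1% (29.2 to 31.1) and 20.9% (20.1 to 21.7). Cells without a class name were 20.0%, 18.7% and 13.8%, and most of them sat in a low-count cluster with median UMIs of 636, 845 and 893, which held 14.0%, 11.3% and 7.18% of cells. A cluster led by MALAT1 and mitochondrial transcripts held 4.22%, 5.08% and 4.50%. A cluster led by CXCL14, WNT6 and GABRP held 1.46%, 1.94% and 1.76%, and its name was withheld by a rule set after its genes were seen. A cluster led by the endocrine genes CHGA, INS and GHRL held 0.320%, 0.407% and 0.353%. At a finer clustering the hepatocyte-like shares were 34.5%, 22.5% and 38.3%, so the near equality of the untreated and oleate shares depended on the clustering.

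The comparison of oleate with untreated organoids asks what a fatty acid load did in the hepatocyte-like cells. APOA4, a lipoprotein component made by intestine and liver, stood at 11109 CPM (counts per 1000000 scaled counts, interval 11088 to 11130) with oleate and 1577 CPM (1570.0 to 1584) without, a log2 difference of 2.82. FABP2, an intracellular fatty acid carrier, stood at 41.7 CPM (40.4 to 43.0) against 6.2 (5.8 to 6.7), and the retinol carrier RBP2 stood at 960 CPM (954 to 966) against 282 (279 to 285). Both are best known from the intestinal epithelium, as is the keratin KRT20, at 23.6 against 3.6 CPM. The acyl-CoA synthetase ACSL5 was higher by a log2 of 2.06 and DGAT2, which catalyses the last step of triglyceride synthesis, by 2.02. HILPDA, an inhibitor of lipid droplet breakdown and a target of hypoxia signalling, went the other way, at 12 CPM (11.3 to 12.7) against 89.4 (87.7 to 91.1), a log2 difference of −2.80.

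Of 5299 genes measured, 61 were at least 2-fold higher and 17 at least 2-fold lower with oleate. Among the furthest genes upward were also S100P (log2 2.29), C11orf86 (2.08), complement C3 (1.77) and the matrix metalloprotease MMP1 (1.76). Furthest downward after HILPDA were GSG1 (−2.64), HOPX (−1.79), the steroid and bile acid sulfotransferase SULT2A1 (−1.56), ERI2 (−1.53), the transcriptional regulator CITED2 (−1.39), the endoplasmic reticulum protein SDF2L1 (−1.26), FAM162B (−1.22), DEPTOR (−1.19) and WNK3 (−1.17). Most hepatocyte-like cells were in cluster 0 in the untreated library (4524 of 6092) and in cluster 1 with oleate (2640 of 4899). Inside cluster 0 alone 21 genes were at least 2-fold higher and 20 lower, and inside cluster 1 alone 25 and 20. APOA4 differed by 1.94 and 1.89 inside the clusters and HILPDA by −2.38 and −3.44.

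**Figure D1:**
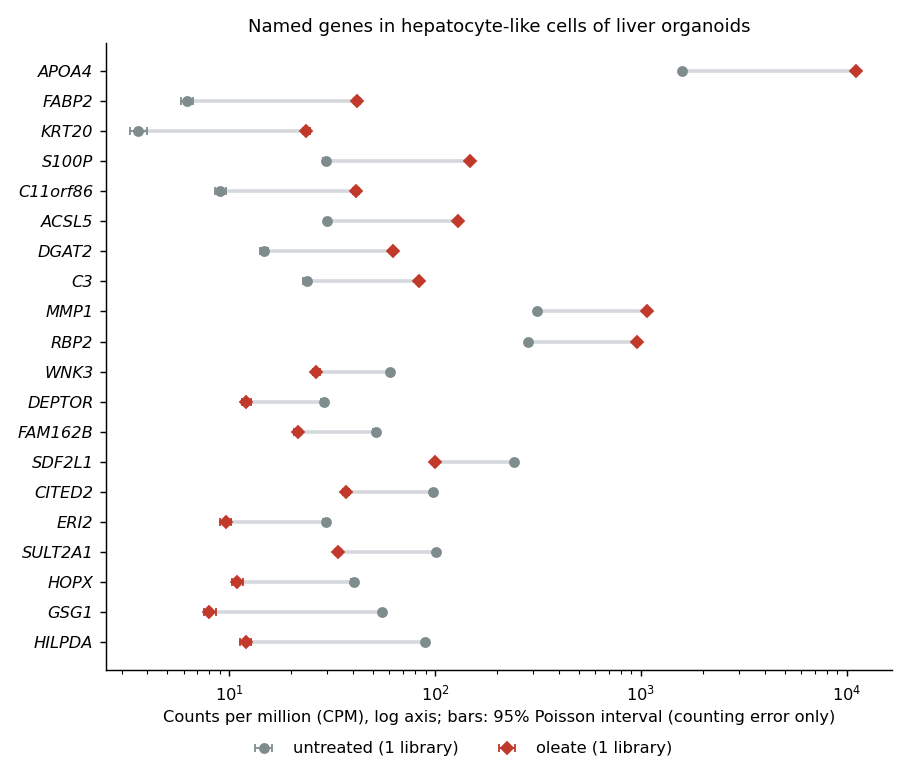
The 20 genes named by size in hepatocyte-like cells, 1 gene per line of the y axis, with their level in CPM on a logarithmic x axis; diamonds are oleate, circles untreated, 1 library each, and bars 95% Poisson intervals for counting error. APOA4 lies at 11109 against 1577 CPM and HILPDA at 12 against 89.4.

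Of 7 measured lipid droplet genes 6 were higher with oleate, with a median log2 difference of 0.94 that lay above all matched random lists (percentile 100), HILPDA being the exception. The droplet coat protein PLIN2 stood at 859 CPM against 416, and CIDEC, which enlarges droplets, at 147 against 46.9. Fatty acid oxidation genes were higher in 13 of 16 (median 0.23, percentile 99.9), with CPT1A, the gate of mitochondrial fatty acid import, at 36.2 against 12.4 CPM and the regulator CREB3L3 at 210 against 73.0. The 5 measured bile acid genes were all higher (median 0.72), among them the bile acid exporter subunit SLC51A (log2 0.99). Of the glucose response list 3 of 6 were higher, all at least 2-fold, TXNIP (1.38) and GPD1 (1.38) among them. The other 3 were lower, among them the glucose transporter SLC2A2 (−0.64). The median of 0.67 (percentile 100) lay between the higher and the lower members, so it does not describe the list as a whole. Unfolded protein response genes were lower in 13 of 18 (median −0.40, percentile 0.0), with the chaperones HSPA5 at 579 against 1201 CPM and HSP90B1 at 532 against 1059. Hypoxia genes were lower in 6 of 7 (median −0.47), with ADM at −0.83 and NDRG1 at −0.62, and the heat shock and dissociation list in 14 of 17 (median −0.21), with FOS at −0.84.

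Apolipoproteins were higher in 8 of 11 (median 0.34), with APOC3 at 3231 CPM against 992 and APOH lower (log2 −0.89). The inflammation list had 6 of 8 higher (median 0.65), with IL32 (1.43) and the chemokine CCL20 (1.24), plasma proteins 7 of 13 (0.10) and oxidative stress genes 10 of 13 (0.15), with SLC7A11 at 0.90. These 4 medians turned negative inside cluster 0 (−0.13, −0.01, −0.30 and −0.04), and those of inflammation (−0.17) and plasma proteins (−0.29) also inside cluster 1. APOC3 itself stood at −0.13 inside cluster 0. Thyroid hormone response genes were higher in 4 of 4 measured, of 20 on the list (0.39, percentile 99.0), and fibrosis genes in 7 of 9 (0.18, percentile 96.8). Of the remaining lists, fatty acid synthesis had 2 of 10 higher (median −0.13), cholesterol synthesis 6 of 20 (−0.08), xenobiotic metabolism a median of −0.17, glycolysis 2 of 13 (−0.15), interferon and nucleic acid sensing (−0.05), p53 response 1 of 7 (−0.15), lysosome (0.09) and mitochondrial transcripts (0.02). Fewer than 3 members of the metallothionein, gluconeogenesis and proliferation lists were measured.

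**Figure D2:**
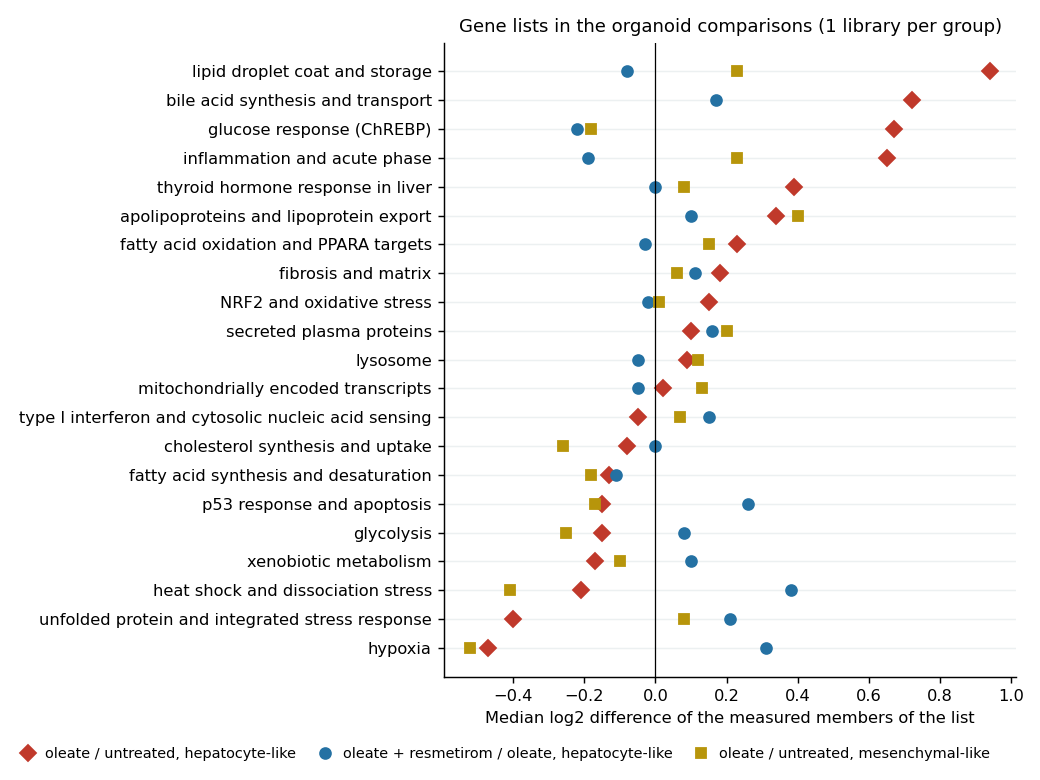
Median log2 difference of the measured members of each gene list on the x axis, with the lists on the y axis; diamonds are oleate over untreated and circles oleate plus resmetirom over oleate in hepatocyte-like cells, and squares oleate over untreated in mesenchymal-like cells. Hypoxia genes stand at −0.47, 0.31 and −0.52 in that order, and lipid droplet genes at 0.94, −0.08 and 0.23.

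The comparison of oleate plus resmetirom with oleate alone addresses what resmetirom, an agonist of the thyroid hormone receptor beta, added in hepatocyte-like cells under fatty acid load. Differences were small: of 5129 genes 8 were at least 2-fold higher and 0 lower. HILPDA stood at 32.9 CPM (31.9 to 33.9) with resmetirom against 11.8 (11.1 to 12.5), a log2 difference of 1.40. The cartilage collagen COL2A1 stood at 182.5 CPM (180.2 to 184.9) against 72.5 (70.9 to 74.2) and the trypsinogen PRSS1 at 53.2 (51.9 to 54.5) against 20.8 (20.0 to 21.7). GEM (1.07), the kinase SGK1 (1.04), SERTAD1 (1.03) and PHLDA2 (1.01) followed, and the remaining gene carried only a clone name. FOXQ1 (0.96), ARL14 (0.95) and the peptidase DPP4 (0.94) were just under 2-fold. Furthest downward were TXNIP at 23.0 CPM (22.1 to 23.8) against 43.4 (42.2 to 44.7), a log2 difference of −0.89, and the growth factor IGF2 at 82.1 (80.5 to 83.7) against 147 (145 to 149), followed by CHST13 (−0.65), ZNF581 (−0.64), S100P (−0.64), PSCA (−0.63), CXCL2 (−0.63), C10orf10 (−0.59), VCAM1 (−0.56) and C3 (−0.55).

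Of the 20 genes on the thyroid hormone response list only 4 were measured, 2 higher and 2 lower (median 0.00, percentile 37.5). The other members of the list were below the gene filter and were not assessed. Heat shock and dissociation genes were higher in all 18 measured (median 0.38, percentile 100), with HSPH1 at 0.69, EGR1 at 0.66 and FOS at 0.59. Unfolded protein response genes were higher in 16 of 18 (0.21), with DDIT4 at 0.66 and ATF3 at 0.61, hypoxia genes in 6 of 7 (0.31), with PDK1 at 0.77 and ADM at 0.72, and p53 genes in 6 of 7 (0.26), with GDF15 at 0.70. Plasma proteins were higher in 11 of 13 (0.16, percentile 99.7), the furthest being the 3 fibrinogen chains FGA (0.84), FGG (0.75) and FGB (0.63). Lipid droplet genes were lower in 6 of 7 (−0.08, percentile 3.7), fatty acid synthesis genes in 8 of 9 (−0.11), the inflammation list in 6 of 8 (−0.19) and the glucose response list in 4 of 5 (−0.22). Without a scaling factor the count past 2-fold was 5 and with a larger pseudocount 4.

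Against untreated organoids, hepatocyte-like cells with oleate plus resmetirom had 57 genes at least 2-fold higher and 11 lower of 5213. FABP2 stood at 43.6 CPM (42.4 to 44.8) against 6.1, APOA4 at 9260 (9243 to 9277) against 1559, and the monoacylglycerol lipase MGLL at 84.6 against 25.5. The matrix metalloprotease MMP1 stood at 1058 CPM (1052 to 1064) against 311 (308 to 314), a log2 difference of 1.76. CA4 (2.26), ACSL5 (2.04), C11orf86 (1.95), MMP10 (1.90), NTS (1.72) and S100P (1.64) were also among the furthest upward. Downward stood GSG1 (−2.24), HOPX (−1.52), HILPDA (−1.40), ERI2 (−1.40), VCAM1 (−1.28), SULT2A1 (−1.28), the sterol-regulated TMEM97 (−1.22), ZNF395 (−1.10), the hepatic regulator FOXA2 (−1.07) and the mevalonate kinase MVK (−1.01). Inside cluster 0 alone 24 genes were higher and 19 lower, and inside cluster 1 alone 19 and 6.

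Lipid droplet genes were higher in 6 of 7 (median 0.86), fatty acid oxidation genes in 15 of 16 (0.18) and apolipoproteins in 10 of 11 (0.57), while cholesterol synthesis genes were lower in 14 of 20 (−0.12) and fatty acid synthesis genes in 9 of 10 (−0.27). Inside cluster 0 the medians of fatty acid oxidation (−0.01) and apolipoproteins (−0.10) turned negative. Among 5154 genes measured in both comparisons with the untreated library, 39 were at least 2-fold higher in both, of 51 with oleate and 49 with oleate plus resmetirom, where independent lists would share 0.485. For lower genes 7 were shared of 17 and 11, against 0.036. The highest overlap in 100 simulations of 3 unchanged libraries was 0 in either direction, but these carried counting error alone, under which 0 unchanged genes passed 2-fold. Part of the overlap above independent lists may come from the shared untreated library, which cannot be split from a shared response.

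Summed over all cells of each library, oleate gave 44 genes at least 2-fold higher and 12 lower of 5596, led by APOA4 (2.74), FABP2 (2.47), S100P (2.22) and MMP1 (1.72) upward and GSG1 (−2.65) and HILPDA (−1.89) downward. Resmetirom added to oleate gave 10 higher and 1 lower of 5428. PRSS1 (1.48), COL2A1 (1.25), PHLDA2 (1.2) and FGA (1.02) stood higher, and the mesenchymal regulator PRRX1 was the gene past 2-fold downward (9.5 against 20.7 CPM), followed by TWIST1 (−0.90), PCOLCE (−0.82) and COL1A2 (−0.81). Mesenchymal-like cells were 20.9% of that library against 30.1%, and fibrosis genes (median −0.38, 10 of 15 lower) and proliferation genes (−0.46, 0 of 11 higher) stood lower beside it. Against untreated organoids, oleate plus resmetirom gave 68 genes higher and 8 lower of 5481, with FABP2 (2.76), APOA4 (2.70) and SLPI (1.80) upward and GSG1 (−2.06) downward.

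In mesenchymal-like cells, a comparison added after the classes were seen, 13 genes were at least 2-fold higher and 10 lower with oleate of 6263 measured, in 2888 against 3154 cells. ANGPTL4, a lipase inhibitor induced by fatty acids, stood at 40.9 CPM (38.3 to 43.6) against 12.4 (11.1 to 13.9), and the amino acid response gene ASNS at 84.7 (81.0 to 88.5) against 39.6 (37.2 to 42.2). DDIT4, a stress-induced inhibitor of growth signalling, stood at 27.9 CPM (25.8 to 30.2) against 96.2 (92.3 to 100.2), a log2 difference of −1.75. Also lower were the kinase PDK1 (−1.51), VEGFA (−1.34), HBEGF (−1.32), CYR61 (−1.2), the glucose transporter SLC2A3 (−1.15), TAC1 (−1.13), ADM (−1.07), EDN1 (−1.06) and FOS (−1.03). APOA4 (2.39), MMP1 (1.95), RBP2 (1.62), APOC3 (1.51), TFF1 (1.38), TFF2 (1.38), KDELR3 (1.11) and A1BG (1.08) were higher. APOA4 was at 972 CPM here against 11109 in hepatocyte-like cells, and a UMI of it was found in 70.8% of untreated and 99.2% of oleate mesenchymal-like cells (median 6474.5 and 7225.5 UMIs per cell), which as a class should lack it, and in 82.9% and 99.8% of hepatocyte-like cells (17758 and 19806). In hepatocyte-like cells RBP2, APOC3, MMP1, TFF1 and TFF2 also stood far higher and differed the same way, TFF1 for example at 3764 against 1769 CPM.

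Hypoxia genes were lower with oleate in 8 of 9 measured in mesenchymal-like cells (median −0.52), glycolysis genes in 14 of 14 (−0.25), heat shock and dissociation genes in 16 of 17 (−0.41), cholesterol synthesis genes in 19 of 21 (−0.26), fatty acid synthesis genes in 9 of 10 (−0.18) and proliferation genes in 18 of 18 (−0.13). Examples are SLC2A1 (−0.99), PFKFB3 (−0.95), EGR1 (−0.89), IER2 (−0.74) and JUNB (−0.74). Clusters 3, 4 and 5 held 1089, 1230 and 835 of the untreated and 1210, 999 and 679 of the oleate cells. Inside each cluster alone these list medians kept their direction, with proliferation at −0.14, −0.05 and −0.21 and hypoxia at −0.49, −0.64 and −0.95, and 27, 21 and 25 genes passed 2-fold. Fatty acid oxidation genes were higher in 10 of 12 (0.15). Apolipoproteins were higher in 8 of 8 (0.40), with APOA1 at 1643 against 995 CPM beside 18391 against 12216 in hepatocyte-like cells, and were not separated from RNA of those cells. PLIN2 stood at 182 CPM against 95.5, beside 859 against 416 there. Adding resmetirom to oleate left 1 gene past 2-fold of 6172, IL1RL1 at 53.2 CPM (49.5 to 57.0) against 23.5 (21.6 to 25.5). With doublet calls kept in the data IL1RL1 stood at 0.93, under 2-fold, 11 other genes passed and DMKN turned to 0.11. Inside cluster 5 alone IL1RL1 turned to −0.56, and it stood at 0.95 inside cluster 3 and 1.79 inside cluster 4. TFPI2 (0.97), PHLDA2 (0.90), FGA (0.82), DDIT4 (0.80), FGG (0.78), EGR1 (0.76), SERTAD1 (0.76), DUSP1 (0.70) and FOS (0.66) were next upward, and IGF1 (−0.87), TXNIP (−0.74), EFEMP1 (−0.62), ASNS (−0.59), CRABP2 (−0.50), DMKN (−0.50), SHMT2 (−0.48), ARHGEF2 (−0.45), FABP7 (−0.44) and LGALS1 (−0.44) downward. In hepatocyte-like cells the fibrinogen chains differed alike at a higher level, FGA at 1915 against 1073 CPM beside 209 against 118 here and FGG at 2466 against 1470 beside 204 against 118, as did PHLDA2 at 328 against 162 beside 30.4 against 15.9. Heat shock and dissociation genes were higher in 15 of 16 (0.27).

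Against untreated organoids, mesenchymal-like cells with oleate plus resmetirom had 14 genes at least 2-fold higher and 4 lower of 6305, and with doublet calls kept 31 and 2, of which 10 were among the first 18. Inside clusters 3, 4 and 5 alone 19, 21 and 27 passed, and IL1RL1 turned to −0.27 inside cluster 5. ANGPTL4 stood at 47.7 CPM against 12.5, FABP1 at 224 against 94.6 and TFF1 at 231 against 76.1, and APOA4 (2.16), MMP1 (1.91), ECE2 (1.41), APOC3 (1.34), RBP2 (1.26), TFF2 (1.24) and IL1RL1 (1.2) were also higher. Most of these stood far higher in hepatocyte-like cells of the same libraries and differed the same way there: FABP1 at 3133 against 1649 CPM, TFF1 at 4223 against 1749, APOC3 at 2694 against 981 and RBP2 at 783 against 279. APOC3 had a UMI in 62.3% of mesenchymal-like cells with oleate plus resmetirom and 34.8% without (median 5774 and 6474.5 UMIs), and in 92.1% and 82.7% of hepatocyte-like cells (16557 and 17758). GFRA1 (−1.10), CYR61 (−1.03), the retinoic acid carrier CRABP2 (−1.03) and FABP7 (−1.02) were lower, followed by DDIT4 (−0.95), CTGF (−0.94), VEGFA (−0.86), SLC2A3 (−0.86), NTRK2 (−0.81) and ADM (−0.80). Glycolysis genes were lower in 14 of 14 (median −0.29) and proliferation genes in 18 of 18 (−0.23).

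In each organoid library 1 of 3 barcodes was far more abundant than the others. The question was how many cells carried 1 barcode, whichever it was. At least 5 UMIs of 1 barcode with at least 60% of all barcode UMIs were found in 31.1% of untreated cells (30.2 to 31.9), 25.5% with oleate (24.6 to 26.4) and 18.5% with oleate plus resmetirom (17.8 to 19.3). More than 1 barcode was found in 0.492%, 0.387% and 0.273%. These shares are over the 11800, 9809 and 11004 cells that passed the filter, doublet calls included. Of the cells with 1 barcode 96.6%, 93.8% and 89.4% carried the abundant barcode, and the rest carried another. By HTODemux 92.2%, 80.8% and 86.6% did. The abundant barcode made up 96.3%, 95.6% and 93.6% of barcode UMIs, with medians of 3, 3 and 2 barcode UMIs per cell. Mesenchymal-like cells carried at least 5 UMIs of it in 39.9% (38.2 to 41.6), 22.4% (20.9 to 24) and 18.1% (16.5 to 19.8), and hepatocyte-like cells in 23.1% (22.0 to 24.2), 18.4% (17.4 to 19.5) and 12.7% (12 to 13.5). In the cluster led by MALAT1 and mitochondrial transcripts the shares were 83.6%, 70.4% and 70%. At a minimum of 20 UMIs the shares of cells with 1 barcode were 3.81%, 4.35% and 2.82%, and by HTODemux 23.3%, 17.3% and 18.7%, so the order of the libraries depended on the rule.

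In the pools the question was whether the barcode told the lines apart. POLYseq cells carried a median of 148 barcode UMIs and TotalSeq cells 37. By the same rule 12.5% (11.9 to 13.2) of POLYseq cells had 1 barcode and 87.1% more than 1, against 39.3% (38.3 to 40.3) and 59.4% of TotalSeq cells. The highest barcode held a median of 29.9% of a POLYseq cell's barcode UMIs and 52.6% of a TotalSeq cell's. When each barcode was first divided by its own median in the library, a rule chosen after the data were seen, 49.5% of POLYseq and 50.9% of TotalSeq cells had 1 barcode, and by HTODemux 55.6% and 53.6%, so the difference between the pools depended on the rule.

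Among cells with 1 barcode whose line was named from the transcriptome, the barcode matched the line in 90.4% of POLYseq cells (913 of 1010, interval 88.4 to 92.1) and 84.9% of TotalSeq cells (2690 of 3168, 83.6 to 86.1). In the POLYseq pool the match was 98.1% of 156 B16-F10, 95% of 443 Hep G2, 91.2% of 102 3T3, 89.8% of 167 MEG-01, 81.0% of 84 HUVEC and 48.3% of 58 ESH9 cells (35.0 to 61.8). For Hep G2 in this pool either the Hep G2 or the high-glucose barcode counted as a match, under every rule and in the total. The Hep G2 barcode alone was in 70.9% of the 443 cells. The TotalSeq pool had no high-glucose barcode. Its 3T3 barcode held 0.155% of barcode UMIs and was assigned to 0 cells under the main rule. The 150 assigned 3T3 cells of its total thus had no match. For both reasons the totals of the pools do not compare alike. By HTODemux the match was 95.1% of 1962 ESH9 (94.0 to 96.0), 95.1% of 652 3T3, 93.8% of 610 HUVEC, 88.0% of 523 B16-F10, 86.1% of 854 Hep G2 and 79.4% of 466 MEG-01 cells. With scaled barcodes it was 94.1% of 1802 ESH9 (92.9 to 95.2), 92.4% of 569 HUVEC, 91.5% of 365 B16-F10, 90.2% of 417 3T3, 90.2% of 803 Hep G2 and 72.3% of 242 MEG-01 cells. Of the 58 ESH9 cells of the main rule, 25 were in a cluster in which 13 carried the mouse embryonic stem cell barcode and 11 the B16-F10 barcode. In the TotalSeq pool the match was 99.8% of 1162 B16-F10, 88.6% of 483 HUVEC, 84.3% of 562 ESH9, 79.0% of 138 Hep G2, 77.1% of 673 MEG-01 and 0 of 150 3T3 cells (upper bound 2.43%), of which 84.7% carried the B16-F10 barcode. By HTODemux it was 100% of 1046 B16-F10, 100% of 919 HUVEC, 97.0% of 438 Hep G2, 88.9% of 803 ESH9, 76.5% of 648 MEG-01 and 16.6% of 307 3T3 cells, and with scaled barcodes 99.9% of 1167, 96.6% of 1128, 91.8% of 367, 83.7% of 590, 49.8% of 460 and 12.5% of 240 in the same order. A cluster that marker genes did not name carried the mouse embryonic stem cell barcode in all 380 assigned POLYseq cells and in 92.2% of 243 TotalSeq cells.

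**Figure D3:**
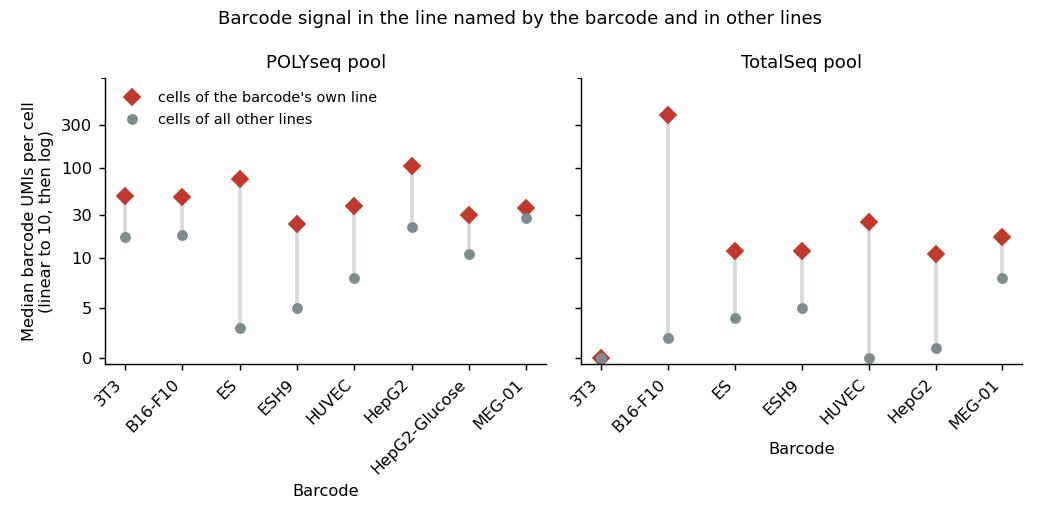
Median barcode UMIs per cell on the y axis, linear up to 10 and logarithmic above, in cells of the barcode's own line (diamonds) and of all other lines (circles), for each barcode on the x axis of both pools; own clusters for the ES, HepG2 and HepG2-Glucose barcodes of the POLYseq pool and for ES in the TotalSeq pool were chosen from the barcodes themselves. MEG-01 in the POLYseq pool stands at 36 against 28, and the 3T3 barcode of the TotalSeq pool at 0 in both.

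The signal over other lines differed between barcodes. In the POLYseq pool the mouse embryonic stem cell barcode had a median of 75 UMIs in its own cluster against 3 elsewhere (rank separation, as the area under the curve, 0.981), ESH9 24 against 5 (0.954), 3T3 49 against 17 (0.915), HUVEC 38 against 8 (0.913), B16-F10 48 against 18 (0.884), Hep G2 105 against 22 (0.811), high-glucose Hep G2 30 against 11 (0.792) and MEG-01 36 against 28 (0.672). In the TotalSeq pool HUVEC had 25 against 0 (0.996), B16-F10 394 against 2 (0.972), Hep G2 11 against 1 (0.932), the mouse embryonic stem cell barcode 12 against 4 (0.865), ESH9 12 against 5 (0.835) and MEG-01 17 against 8 (0.823). The 3T3 barcode was at a median of 0 in both (0.611). ESH9 cells were 28.3% of the POLYseq and 18.6% of the TotalSeq pool, MEG-01 12.1% and 18.1%, Hep G2 16.6% and 6.97%, HUVEC 7.97% and 12.8%, B16-F10 9.38% and 13.1%, 3T3 8.61% and 11.6%, the unnamed cluster above 12.1% and 14.5%, and other unnamed cells 4.96% and 4.32%.

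Each human line was compared between the pools to ask whether the vector left a mark on its transcripts. Only cells without a second barcode were used, those with no barcode or the single barcode of another line included. This kept 63 of 3235 POLYseq and 584 of 1676 TotalSeq ESH9 cells. In HUVEC it kept 84 of 912 and 483 of 1155, and in MEG-01 167 of 1387 and 680 of 1631. The cells compared may therefore not stand for their line. In HUVEC (84 against 483 cells) 26 genes were at least 2-fold higher with POLYseq and 19 lower of 6062, 30 and 13 without a scaling factor, and 24 and 8 with a pseudocount of 5. With the HUVEC barcode alone (68 against 428 cells) 11 genes were higher and 37 lower, and most of the hepatic excess below was absent: ALB stood at 0.06, RBP4 at 0.03, C3 at 0.23, GPC3 at 0.43 and APOA1 at 1.18, and APOB (−0.98) and AKR1C1 (−0.77) turned. Of the 84 cells 4 carried the Hep G2 and 1 the high-glucose Hep G2 barcode. With cells of more than 1 barcode included 29 were higher and 1 lower, and with the scaled barcode rule 8 and 7, under which AKR1C1 turned to −0.31. Transcripts abundant in Hep G2 cells led: albumin (ALB) stood at 628 CPM (584 to 674) against 121 (113 to 130), GPC3 at 88.9 (72.9 to 107.3) against 8.4 (6.4 to 10.8), and APOA1 (2.88), APOB (2.67), C3 (2.66), APOA2 (2.52), RBP4 (2.47) and TF (2.05) were higher, beside DHRS2 (3.42) and AKR1C1 (2.33). CRYAB, a small heat shock protein, stood at 8.2 CPM (3.9 to 15.1) against 47.4 (42.6 to 52.7), and ACTA2 (−1.50), AP3M1 (−1.37), AFTPH (−1.33), ZNF32 (−1.27), S100A4 (−1.18), USP40 (−1.18), MAP4K2 (−1.17), COL1A2 (−1.16) and LEPRE1 (−1.15) were lower. Proliferation genes were higher in 17 of 17 (median 0.46), with CDK1 at 0.75, and fibrosis genes lower in 13 of 14 (−0.43). The same hepatic transcripts stood higher in every other line of the POLYseq pool, the mouse lines included: over 12 hepatic genes the log2 difference was 2.13 in 3T3, 2.10 in B16-F10, 1.95 in ESH9, 1.86 in HUVEC and 1.85 in MEG-01, and 0.41 in Hep G2 itself.

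**Figure D4:**
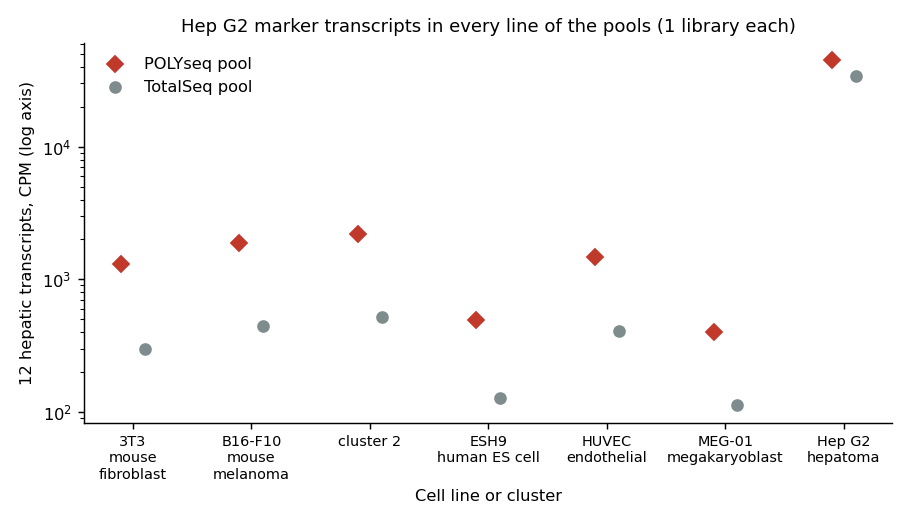
Summed CPM of 12 hepatic genes on a logarithmic y axis, for each line or cluster on the x axis, with diamonds for the POLYseq and circles for the TotalSeq pool; cluster 2 is the unnamed cluster with the mouse embryonic stem cell barcode. 3T3 cells stand at 1307 against 299 CPM and Hep G2 cells at 45126 against 34026.

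MEG-01 cells (167 against 680) had 14 genes higher and 4 lower of 5491. The immediate early gene FOS stood at 49.8 CPM (42.5 to 58.0) against 7.1 (5.9 to 8.4), with FOSB (1.91) and NR4A2 (1.57) of the same kind. The hepatic genes APOA1 (2.67), APOB (2.31), SERPINA1 (1.86), AHSG (1.48), ALB (1.44) and APOA2 (1.21) were higher, as was STC1 (1.33). CRYAB (−1.36), MT1M (−1.26) and NEFH (−1.10) were lower, followed by SLC25A4 (−0.97), HIST3H2A (−0.92), RPSAP58 (−0.92), TIMP2 (−0.90), PCSK7 (−0.90), GNG11 (−0.88) and MTO1 (−0.85). Mitochondrial transcripts were higher in 13 of 13 (median 0.21) and lysosome genes in 9 of 11 (0.19). With the MEG-01 barcode alone (150 against 519 cells) the counts were 14 and 4 again, but HIST3H2A (0.62), MT1M (0.64), CRYAB (0.48), RPSAP58 (0.14) and SLC25A4 (0.13) turned. With cells of more than 1 barcode included they were 13 and 1. With a mitochondrial limit of 10% they were 6 and 11 and STC1 turned to −0.86, and under the scaled barcode rule CRYAB (0.39), MT1M (0.19), TIMP2 (0.46), SLC25A4 (0.24) and RPSAP58 (0.05) turned.

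Hep G2 cells without the high-glucose barcode (340 against 149) had 18 genes higher and 5 lower of 5569. The metallothionein MT1G stood at 26.9 CPM (22.1 to 32.4) against 1.6 (0.4 to 4.0), the iron hormone HAMP at 60.8 (53.5 to 68.8) against 8.6 (5.4 to 13) and FABP1 at 232 (217 to 247) against 90.1 (78.8 to 102.5), and ANKRD37 (2.49), MT1E (2.17), FOS (1.94), LEAP2 (1.72), MT1X (1.63), TXNIP (1.41) and STMN2 (1.21) were higher. The fibrinogen chain FGB stood at 40.2 CPM (34.3 to 46.8) against 88.5 (77.4 to 100.9), and the melanocyte gene TYRP1 (−1.72), GSTA1 (−1.18), CRYAB (−1.04), KLC2 (−0.99), MT1M (−0.88), EDA2R (−0.85), GTPBP1 (−0.79), BCL2L2 (−0.74) and ZBED3 (−0.73) were lower. Metallothioneins were higher in 4 of 5 (median 1.63) and glycolysis genes in 11 of 14 (0.27), and plasma proteins were lower in 14 of 16 (−0.16). Cluster 7, where the high-glucose cells lay, held 9.12% (6.28 to 12.7) of the POLYseq cells and 1.34% (0.163 to 4.77) of the TotalSeq cells compared. With the scaled barcode rule 9 genes were higher and 3 lower, 4 of them shared with the first list, and STMN2 (−0.69), TYRP1 (2.13), CRYAB (1.17) and MT1M (0.60) turned. With the Hep G2 barcode alone (314 against 109 cells) 24 were higher and 6 lower, and TYRP1 (1.6), CRYAB (0.91) and MT1M (0.87) turned. With cells of more than 1 barcode included 157 were higher and 12 lower, and FGB (0.05), TYRP1 (0.07), CRYAB (0.65) and MT1M (1.23) turned. Only cells whose highest barcode, scaled to its median, was the high-glucose barcode were left out of this set. Cluster 7 held 1201 cells of the whole POLYseq and 7 of the whole TotalSeq pool, so high-glucose cells may have stayed in it. Inside cluster 6 alone 4 genes were higher and 7 lower, HAMP stood at 0.95, MT1G at 1.79 and FOS at 1.75, and FABP1 (−0.11) and LEAP2 (−0.05) turned.

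ESH9 had 63 against 584 cells, and of 5949 genes 15 were higher and 49 lower, but 28 genes passed in simulated data of this depth with no difference. AHSG stood at 128.5 CPM (103.8 to 157) against 11 (8.7 to 13.7) and ALB at 238 (204 to 276) against 42.7 (38.1 to 47.7), with SERPINA1 (3.24), APOA2 (2.17), STMN2 (2.09), IGFBP1 (1.84), HIST3H2A (1.62), FN1 (1.42), MT1M (1.31) and MKRN1 (1.18). A cluster in which HIST3H2A reached 2272 and 2697 CPM, against 19.5 and 22.4 in the main ESH9 cluster, held 39.7% (27.6 to 52.8) of the POLYseq cells compared and 9.76% (7.48 to 12.5) of the TotalSeq cells. This was the cluster with mouse embryonic stem cell and B16-F10 barcodes, at median UMIs of 13183 and 14752 against 10140 and 11707 in the main cluster, and whether it held droplets with cells of more than 1 line was not tested. IGLL5 had 0 counts against 467 and was at least 15.7-fold lower, and it came from a low-count cluster (median UMIs 1950 and 1728, mitochondrial share 0.381% and 0.368%, against 7.92% and 7.96% in the main cluster) at 460 and 1803 CPM, with 0.075 and 0 CPM in the main cluster. The other genes furthest downward had 4 to 14 counts in the POLYseq cells: KIAA1244 (−1.77), ZMAT3 (−1.56), IDO1 (−1.54), RAP1GDS1 (−1.50), ARFGAP3 (−1.46), PPAP2A (−1.43), INTS3 (−1.42), RAB12 (−1.41) and HIST1H2AJ (−1.39). Inside the main cluster alone 11 genes were higher and 161 lower in 32 against 495 cells, ALB stood at 2.51, HIST3H2A at 0.91, MKRN1 at 0.60 and MT1M at −1.96. With the ESH9 barcode alone (28 against 474 cells) 9 were higher and 207 lower. There ALB stood at 2.29, and HIST3H2A (−1.67) and MT1M (−0.41) turned. A gene could enter through the larger TotalSeq group alone. The minimum count asked for a higher CPM in the smaller POLYseq group. The excess of lower genes, 161 and 207 included, was therefore not separated from the gene filter. For the 63 cells 97 were higher and 431 lower with 5 CPM and 20 counts, but 764 and 496 with no filter. The simulation did not cover the sets of 32 and 28 cells. At a pseudocount of 5 the counts for the 63 cells were 12 and 18. With cells of more than 1 barcode included 9 genes were higher and 2 lower, and HIST3H2A (−0.25), ZMAT3 (0.27), IDO1 (0.03) and KIAA1244 (0.02) turned, while under the scaled barcode rule STMN2 (−0.51), MKRN1 (−0.21) and IGLL5 (0.08) turned too. The list of interferon and nucleic acid sensing genes, of interest for a DNA vector, had few of its 22 members measured. Its medians were −0.36 in ESH9 (4 measured), −0.12 in HUVEC (8), 0.15 in Hep G2 (4) and −0.07 in MEG-01 (5). None lay outside the central 95% of random lists.

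The high-glucose culture was compared with standard Hep G2 in the POLYseq pool to ask what the glucose load did, by barcode, in 107 against 314 cells. Whether the cultures differed in more than glucose, in medium, density or passage, is not given in the sources used here. Hypoxia and glycolysis genes were higher: the carbonic anhydrase CA9 stood at 77.6 CPM (63.5 to 94.0) against 6.2 (3.8 to 9.4), the glycolytic regulator PFKFB4 at 56.2 against 4.4, and SLC2A3 at 314 (285 to 346) against 42 (35.4 to 49.4). The secreted phospholipase PLA2G2A stood at 102 CPM (85.7 to 120.5) against 2.3 (1.0 to 4.6) and TNNI2 at 620 (579 to 664) against 45.8 (38.9 to 53.6). The water and glycerol channel AQP3 stood at 6.7 CPM (3.0 to 12.6) against 256.5 (239.8 to 274), a log2 difference of −5.07, and the steroid carrier SHBG at 3.7 (1.2 to 8.6) against 52.0 (44.6 to 60.2). TXNIP, a glucose-induced inhibitor of glucose uptake, stood at 157 CPM (136 to 179) against 19.4 (15 to 24.6).

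Of 5696 genes 317 were at least 2-fold higher and 584 lower. The median gene stood at −0.23. Without a scaling factor the counts were 471 and 305, and with the scaled barcode rule 571 and 455. With no filter beyond 1 count they were 1399 and 1043. The balance of directions therefore depended on the scaling, the barcode rule and the gene filter. MT1E (3.38), ANGPTL4 (3.38), haptoglobin (HP, 3.34), LEAP2 (3.19), MT1G (3.17) and TMEM37 (3.05) were also among the furthest upward. Downward stood AREGB (−5.10, 2 counts, 1.5 CPM with an interval of 0.2 to 5.3), a paralog of AREG with which reads may be shared, VGF (−4.14, 1 count, 0.0 to 4.1 CPM), C5AR1 (−4.07), LCN2 (−3.71), KCNMB3 (−3.63), MXD1 (−3.62), PDIA2 (−3.39, 4 counts) and PHLDA2 (−3.31). Of the assigned high-glucose cells 98.1% (93.4 to 99.8) and of the standard cells 4.14% (2.22 to 6.98) lay in cluster 7.

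**Figure D5:**
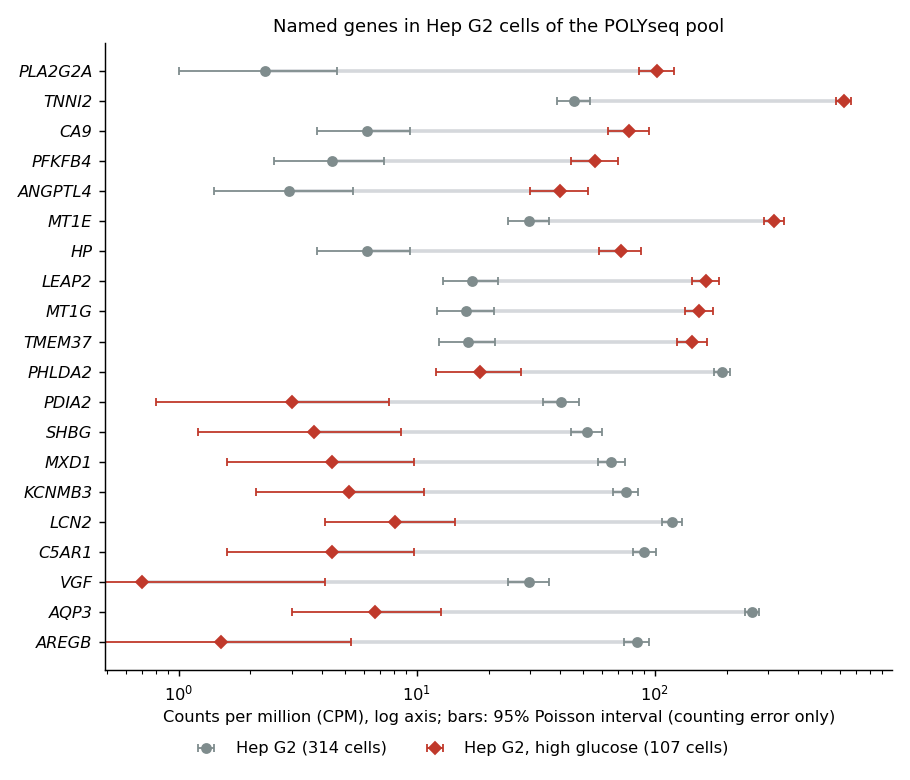
The 20 genes furthest apart between Hep G2 with high glucose (diamonds) and standard Hep G2 (circles), 1 gene per line of the y axis, with their level in CPM on a logarithmic x axis; bars are 95% Poisson intervals for counting error, and those of VGF and AREGB run off the left edge. PLA2G2A lies at 102 against 2.3 CPM and AQP3 at 6.7 against 256.5.

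Hypoxia genes were higher in 12 of 13 (median 1.76), with ANKRD37 at 2.54, and glycolysis genes in 13 of 14 (1.06), with PGK1 at 1.56 and LDHA at 1.47. All 5 measured genes of the glucose response list were higher (1.08), among them G6PC (1.60), and all 5 metallothioneins (2.5). Proliferation genes were higher in 13 of 13 (1.69), with MKI67 at 112 CPM against 15. Cholesterol synthesis genes were higher in 10 of 11 (0.67), fatty acid synthesis genes in 4 of 7 (0.72), with SCD at 1.97, fatty acid oxidation genes in 9 of 13 (0.52), with FABP1 at 2.64, and apolipoproteins in 8 of 12 (0.45), with APOA5 at 2.68 and APOC3 at 2.43. Unfolded protein response genes were lower in 18 of 19 (−1.66), with HSPA5 at 743 CPM against 4527, SDF2L1 at −2.87 and DDIT3 at −2.54. Oxidative stress genes were lower in 16 of 18 (−1.12), with SLC7A11 at −2.95, p53 genes in 11 of 11 (−0.80), with GDF15 at −2.97, heat shock and dissociation genes in 12 of 15 (−0.67) and bile acid genes in 6 of 9 (−1.02). Gluconeogenesis genes had a median of −0.48 over 3 measured members. Plasma proteins, with a median of 0.16, stood at −0.08 when the control cells came from the TotalSeq pool.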

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

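Each test in this part was chosen after the result it addresses was seen, but the bounds for depth and for HUVEC cells rich in hepatic transcripts were written before their values. The test of depth replaced an earlier one, thinning (median 1.29), which could hardly move summed CPM. Single libraries per group gave no group of samples large enough to look for a sample apart from the others.

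A small cluster of the cell line pools carried transcripts of lung cells, though no lung sample is named among the lines, and this was singled out as a signal outside the comparisons. It held 74 cells in the POLYseq pool (0.647%) and 103 in the TotalSeq pool (1.14%), and its level of SFTPC, a surfactant protein of the lung alveolus, was 4889 CPM and 2831 CPM, against 0.02 and 0 CPM in other cells. The airway genes SLPI (3694 and 2143 CPM) and SCGB3A1 (2251 and 1482), the macrophage gene C1QB (1174 and 900) and SFTPA1 (894 and 549) were found beside it, at median UMIs of 776 and 840 per cell. At least 5 UMIs of a barcode other than the library's most abundant 1 were found in 1.66% of untreated cells, 2.18% with oleate and 2.35% with oleate plus resmetirom.

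Genes at least 2-fold higher with oleate in hepatocyte-like cells could come from a different mix of clusters 0 and 1, from free RNA of other cells or from depth. The clusters were called from the same counts without batch integration. A shift between them was therefore not separated from a difference with oleate, and values inside a cluster may leave part of that difference out. The mix is argued against as the whole cause by a median log2 difference of 0.82 inside cluster 0 and 0.90 inside cluster 1, against 1.275 in all these cells, with 60 of the 61 genes higher inside both clusters, though it may carry part of the size, since 21 and 23 of them passed 2-fold there. Free RNA is argued against by the gain in mesenchymal-like cells, a median of 8.26% of that in hepatocyte-like cells. The test of depth fell between the bounds set. The genes stood higher in the cells above the median depth of each library than in those below. The difference was 0.59 in untreated and 0.70 in oleate cells (median UMIs 24190 against 12874 and 26492 against 14068). These sets of cells mixed the clusters, whose depths differed. The libraries had medians of 17758 and 19806. Inside cluster 0 median UMIs were 16050 untreated and 16251 with oleate, and inside cluster 1 24942 and 24232.5. The differences of 0.82 and 0.90 inside these clusters, at near equal depth, argue against depth as the whole cause there. Preparation of 1 library per group was not separated from oleate, nor albumin if, as the labels leave open, the untreated organoids received none.

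Hepatic transcripts were higher in the other lines of the POLYseq pool than in those of the TotalSeq pool. Free RNA from Hep G2 cells is a candidate explanation: the lowest log2 difference over the 3 mouse groups, whose own genes are not in the matrix, was 2.10. Hep G2 cells made up 16.6% of the POLYseq and 6.97% of the TotalSeq pool. In HUVEC cells with the HUVEC barcode alone most of the excess was absent. The 5% of HUVEC cells richest in these transcripts, however, held 76.7% of the hepatic UMIs in the POLYseq and 80.7% in the TotalSeq pool. The sum over cells with the HUVEC barcode can therefore turn on which rich cells it held, and does not speak for or against free RNA. Without the 5% of HUVEC cells with the most UMIs of these transcripts the log2 difference was 2.165. In ESH9 cells with the ESH9 barcode alone ALB stayed higher. Doublets are argued against as the whole cause by a median of 2.17 after the 5% of cells richest in these transcripts were left out. In HUVEC, however, this took the level from 1476 to 366 and from 406 to 81.5 CPM, and doublets stay open there, as the rich cells had 1.44 and 1.08 times the median UMIs of the others. A response of the human lines to the vector is argued against by a difference of −0.24 between human and mouse lines, where a response would need the human lines to stand higher.

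Most cells of the POLYseq pool had no single barcode in the majority. Barcode shared by all cells of the pool is a candidate explanation: the counts of barcodes not a line's own had a median correlation of 0.996 over pairs of lines, the lowest of 21 pairs being 0.987. Each correlation was over 5 or 6 barcodes of unequal abundance. Doublets drawn from the whole pool could give it too, so the correlation does not tell these apart. Doublets are argued against by gene UMIs in cells with more than 1 barcode at 0.949 times those of cells with 1 (0.753 to 1.03 over the lines), where doublets would hold more. Whether the barcode moved between cells before or after pooling was not tested, and no biological explanation was tested.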

How the results depend on the processing

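The gene filter, scaling, size rule, gene lists and the rule for genes named by size were set before the data were examined. The limit on list examples, the withholding of cluster names for certain leading genes, the comparison of mesenchymal-like cells, and the settings with cluster 0, 1, 3, 4 or 5 alone, with a line's own barcode alone, pool cluster 0 or 6 alone, without the low-count clusters, with all cells of a line, with barcodes scaled to their medians and with control cells from the TotalSeq pool, were chosen after seeing the data. No paired analysis was possible because each group had 1 library. Leaving out each barcode group in turn was not run, since each organoid library carried 1 barcode, and the match of barcode and line over all cell barcodes was not run, since cells outside the filter were not clustered. Of 216 alternative values of the main results 114 stayed within the interval or within 1.5 times the main count and 102 moved. Of 2940 values for the 280 genes named by size 2160 stayed, 736 moved and 44 reversed, of 2427 values for the list examples 1833 stayed, 584 moved and 10 reversed, and of 3100 list medians 2741 stayed, 335 moved and 24 reversed. DESeq2 size factors moved none of the 14 counts, CPM with no factor 1 and thinning to 5000 UMIs per cell 0 of 3, which says little of depth since summed CPM do not scale with it. In simulated data with counting error alone 28 unchanged genes passed for ESH9 and 8 for high glucose, against 0 for MEG-01 and each organoid comparison. Where no cause is given below, the cause was not tested.

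Looser gene filters tested more genes, which raised the counts by construction. With 5 CPM and 20 counts the genes past 2-fold in hepatocyte-like cells were 130 for oleate against untreated, 20 for oleate plus resmetirom against oleate and 121 for oleate plus resmetirom against untreated. In the same order they were 99, 27 and 129 in all cells and 51, 5 and 43 in mesenchymal-like cells, and 528 in ESH9, 286 in HUVEC, 119 in Hep G2, 67 in MEG-01 and 1559 for high glucose. With no filter beyond 1 count they were 164, 32 and 148, then 116, 36 and 152, then 61, 7 and 58, and in the lines 1260 (ESH9), 858 (HUVEC), 364 (Hep G2), 205 (MEG-01) and 2442 (high glucose). The balance of directions turned in some of these. HUVEC had 94 genes higher and 192 lower with 5 CPM and 20 counts, but 571 and 287 with no filter. With no filter ESH9 had 764 higher and 496 lower, and high glucose 1399 and 1043. At a pseudocount of 5, which shrinks differences at low levels by construction, resmetirom added to oleate gave 4 genes in hepatocyte-like cells and 7 in all cells, ESH9 30 and Hep G2 14. With CPM and no factor resmetirom added to oleate gave 5 in hepatocyte-like cells.

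For oleate in hepatocyte-like cells the count was 48 at cluster resolution 1.2, 41 in cluster 0 alone and 45 in cluster 1 alone, and for oleate plus resmetirom against untreated 43 in cluster 0 and 25 in cluster 1. With Scrublet calls kept, mesenchymal-like cells gave 11 genes for resmetirom added to oleate and 33 for both against untreated, and resmetirom added to oleate gave 3 in cluster 4 alone and 8 in cluster 5 alone. With its own barcode alone ESH9 gave 216. With all cells of the line ESH9 gave 11. Hep G2 gave 169, a set that left out only cells whose highest scaled barcode was the high-glucose barcode. With scaled barcodes ESH9 gave 12, HUVEC 15 and Hep G2 12. In pool cluster 0 alone ESH9 gave 172 and in pool cluster 6 alone Hep G2 11.

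Hepatocyte-like shares of untreated, oleate and oleate plus resmetirom libraries were 34.5%, 22.5% and 38.3% at resolution 1.2, 62.2%, 58.3% and 71.2% with at least 2000 UMIs, 50.5%, 48.7% and 62.4% with Scrublet calls kept, and 64.5%, 61.1% and 74.0% without the low-count clusters 2 and 6. With a mitochondrial limit of 10% the oleate share was 49.4%. Mesenchymal-like shares were 25.5%, 28.3% and 19.8% at resolution 1.2, 30.7%, 33.1% and 22.0% with 2000 UMIs, 29.4%, 32.4% and 23.6% with Scrublet calls kept, 33.4%, 36.0% and 23.6% without clusters 2 and 6, and 28.9%, 33.0% and 22.9% at 10%. Leaving out clusters or low cells raises the other shares by construction.

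Cells with 1 barcode in the untreated, oleate and oleate plus resmetirom libraries were 29.8%, 24.2% and 17.4% at a share of 80%, 3.81%, 4.35% and 2.82% at 20 UMIs, 37.8%, 29.4% and 21.4% over all cell barcodes, and 11.6%, 11.8% and 11.9% with scaled barcodes. HTODemux gave 23.3%, 17.3% and 18.7%, so that oleate plus resmetirom stood above oleate. The POLYseq pool gave 3.37% at 80%, 55.6% by HTODemux and 49.5% with scaled barcodes, and the TotalSeq pool 21.2%, 53.6% and 50.9%, and 36.6% at 20 UMIs. The match of barcode and line at 80% was 95.7% in the POLYseq and 80.5% in the TotalSeq pool, and 87.7% in the latter by HTODemux. At 80% the POLYseq match was 100% of 57 B16-F10, 98.6% of 146 Hep G2 and 98.1% of 54 MEG-01 cells. It was 85.7% of 7 3T3, 57.1% of 7 HUVEC and 16.7% of 6 ESH9 cells. The TotalSeq match was 99.9% of 1150 B16-F10, 75.4% of 179 ESH9 and 63.2% of 114 HUVEC cells. It was 42.5% of 226 MEG-01, 33.3% of 30 Hep G2 and 0% of 118 3T3 cells. Stricter shares and minimums assign fewer cells by construction.

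In hepatocyte-like cells with oleate the medians of apolipoproteins (−0.005) and plasma proteins (−0.11) reversed at resolution 1.2. In cluster 0 alone apolipoproteins (−0.13), plasma proteins (−0.30), oxidative stress (−0.041), inflammation (−0.009), APOC3 (−0.13), SLC51B (−0.13) and ICAM1 (−0.15) reversed, and in cluster 1 alone plasma proteins (−0.29), inflammation (−0.17) and SAA1 (−0.20). For oleate plus resmetirom against untreated, cluster 0 alone reversed fatty acid oxidation (−0.007), apolipoproteins (−0.10), plasma proteins (−0.10), inflammation (−0.36) and APOC3 (−0.26), and cluster 1 alone inflammation (−0.42). A mitochondrial limit of 10% reversed mitochondrial transcripts for resmetirom added to oleate (0.008) and plasma proteins for oleate in all cells (−0.028). In mesenchymal-like cells Scrublet calls kept reversed plasma proteins with oleate (−0.074) and DMKN for resmetirom added to oleate (0.11). Cluster 5 alone reversed IL1RL1 (−0.56) and the unfolded protein median (−0.001) for resmetirom added to oleate and IL1RL1 (−0.27) for both against untreated.

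In ESH9 all cells of the line reversed HIST3H2A (−0.25), IDO1 (0.027), ZMAT3 (0.27), KIAA1244 (0.016), HERPUD1 (−0.011), MT1E (0.052), BNIP3 (0.06) and the unfolded protein (−0.015), metallothionein (0.052), proliferation (0.02) and hypoxia (0.01) medians. Scaled barcodes reversed STMN2 (−0.51), HIST3H2A (−1.84), MT1M (−0.16), MKRN1 (−0.21), ZMAT3 (0.30), KIAA1244 (0.15), IGLL5 (0.076) and the proliferation median (0.005), pool cluster 0 alone MT1M (−1.96), and the own barcode alone HIST3H2A (−1.67) and MT1M (−0.41). In HUVEC scaled barcodes reversed AKR1C1 (−0.31), and the own barcode alone APOB (−0.98), AKR1C1 (−0.77) and MT1M (0.69). In Hep G2 all cells of the line reversed MT1M (1.23), CRYAB (0.65), FGB (0.05), TYRP1 (0.065) and SREBF2 (0.034), scaled barcodes reversed STMN2 (−0.69), MT1M (0.60), CRYAB (1.17), TYRP1 (2.13) and the fibrosis median (−0.02), pool cluster 6 alone LEAP2 (−0.045) and FABP1 (−0.11), and the own barcode alone MT1M (0.87), CRYAB (0.91) and TYRP1 (1.6). In MEG-01 a mitochondrial limit of 10% reversed STC1 (−0.86), and scaled barcodes TIMP2 (0.46), RPSAP58 (0.054), SLC25A4 (0.24), MT1M (0.19) and CRYAB (0.39), and the own barcode alone RPSAP58 (0.14), HIST3H2A (0.62), SLC25A4 (0.13), MT1M (0.64) and CRYAB (0.48). For high glucose the control cells from the TotalSeq pool reversed the plasma protein median (−0.081).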

Other observations

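No test was run in this part, which gives gene groups not described above, and all of its comparisons have 1 library per group. In Hep G2 of the POLYseq pool against the TotalSeq pool, proliferation genes (median log2 difference 0.27) and hypoxia genes (0.18) were higher in 9 of 9 measured, cholesterol synthesis genes in 9 of 11 (0.26) and mitochondrial transcripts in 12 of 13 (0.21). The cell cycle genes CCNB1 (0.95), TOP2A (0.67) and CENPF (0.62) and the metallothionein MT2A (0.98) are examples. Pool cluster 7 held 9.12% of the POLYseq and 1.34% of the TotalSeq cells compared, and inside pool cluster 6 alone the medians were 0.06 for proliferation, 0.09 for hypoxia, 0.17 for cholesterol synthesis and 0.22 for mitochondrial transcripts. In HUVEC lysosome genes were lower in 14 of 15 (−0.29) and 2 of 3 metallothioneins were higher (0.72), MT2A standing at 2976 against 1807 CPM. Apolipoproteins were higher in 5 of 6 (2.09) and plasma proteins in 6 of 6 (2.02) in the same cells, but stood at 0.14 and 0.04 in cells with the HUVEC barcode alone, where the lysosome median was −0.30. In ESH9 hypoxia genes were lower in 8 of 8 (−0.41) and glycolysis genes in 13 of 15 (−0.22), while the hypoxia median stood at 0.01 when cells with more than 1 barcode were included.

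In the hepatocyte-like cells of organoids with oleate plus resmetirom against untreated organoids, plasma proteins were higher in 10 of 13 (0.28), with FGB at 0.78 and FGA at 0.65, and oxidative stress genes in 11 of 14 (0.24). The plasma protein median stood at −0.10 inside cluster 0. Fibrosis genes were higher in 7 of 8 (0.31), TIMP3 (0.70) and TAGLN (0.64) among them, and unfolded protein response genes were lower in 10 of 17 (−0.16), with SDF2L1 at −0.96 and HSPA5 at −0.70. The glucose response list had 4 of 6 higher (0.49), with GPD1 at 1.22. The thyroid hormone response list had 4 of 4 measured genes higher, of 20 on the list (0.41). In high-glucose Hep G2 the lysosome list was lower in 11 of 13 (−0.54) beside a median gene at −0.23, and the bile acid transporters ABCB4 (−1.93) and ABCC2 (−1.54) stood lower.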
